A study of Homo sapiens with 14 samples.

How the data were processed

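The series measured RNA of sorted human blood stem and progenitor cells on Affymetrix U133 Plus 2.0 arrays, 1 array per sample, 14 in all. Per the labels' protocols, cells were sorted by surface proteins. Fetal liver (FL) cells, fetal liver cells kept on the mouse stroma line OP9-M2 (FL-OP9) and embryoid body cells kept on that stroma (EB-OP9) were CD34+CD38-CD90+CD45+. Embryoid body (EB) cells, grown from the embryonic stem cell line H1, and placenta (PL) cells were sorted with CD43 in place of CD45. The labels do not say whether replicates were separate donors or separate cultures, so every p-value measures only the spread between these samples.

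The deposited table holds 1 intensity per probe set and array, on a linear scale, after a normalization between arrays by the authors whose kind is not stated. Per the submitters' processing notes limma was used, with no version given. Column medians ran from 178 to 206. The log base behind the table is open. The largest value of an array lay between 1.83e+06 and 2.88e+06, above the 65535 that a 16-bit scanner can give, and 1.68% to 2.17% of the probe sets of each array exceeded that limit. The natural logs of the values spanned 1.10 to 14.9, a range usual for log2 summaries. If the table is e to the power of log2 values, each log2 difference below is 1.4427 times too large, and the difference of natural logs, called the natural-log reading below, is the true one. The choice leaves directions and ranks nearly alone but sets every stated size.

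Of 54675 probe sets, 62 were controls, 11721 had no gene symbol and 1801 had several, and these were left out. XIST, TSIX and Y-linked genes were left out of every step. The other 41003 probe sets covered 19726 genes. For the 10503 genes with over 1 probe set, the one with the highest mean over all arrays was used. Values were taken as log2 of the value plus 1. The control level was the 95th percentile of 27 probe sets for Bacillus genes not added to the samples, 5.37 log2 units as the mean over arrays. Where one group of a comparison lay below that level, the difference from the level is given as "at least". Members below it in both groups were given no difference of their own. Arrays have no counting depth, so their number limits the precision.

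One linear model of 6 groups was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes; 8 residual degrees of freedom and 3.59 more from the prior), so that groups of 2 and 3 shared one estimate of the spread. Weights that limma estimated per array were 0.24 in PL, 0.47 in EB, 1.22 in EB-OP9 and 0.66 to 4.16 in FL and FL-OP9. PL and EB arrays thus varied more. By these weights the stated SEs and p-values are too small for EB against PL and PL against FL. They are too large for comparisons among FL and FL-OP9 arrays. Genes with a Benjamini-Hochberg adjusted p under 0.05 in limma's two-sided moderated test are called changed. Differences are given with their standard error (SE) from this model, group levels with their standard deviation (SD). There were 9 comparisons, 6 main and 3 secondary, each adjusted by itself. The secondary ones were FL-OP9 at 5 weeks against FL, EB-OP9 against FL, and the difference between the culture effects of EB and FL cells. Recovery was tested on simulated data with 50 changed genes of each size in each main comparison. At a change of 2 log2 units 40% to 70% of the changed genes were found, at 4 units 80% to 96%. These shares belong to simulations in which 103 to 135 genes passed. A comparison with fewer calls needs a smaller unadjusted p and finds less.

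Lists of genes for blood lineages, for other cell types that a sort could let through, for developmental stage and for signalling, stress and metabolic programs were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. In the results each list is given with the count of members past the test over all genes and with the count adjusted over the list alone. Of 261 list tests 131 passed. Of these 21 passed with a correlation estimated per list, and camera p-values below are followed by that value. The tool fry, which asks whether a list's genes move one way on balance, called 91 of the 261. The HOXA cluster is not analysed here as a list, since 1 of its 11 genes had a probe set with a single symbol. The study singled out genes of that cluster, so their direction would not be independent evidence.

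Genes to name were set by rule. For each main comparison these were the 10 largest rises and the 10 largest falls among genes past the test, with a log2 difference of at least 1, group values that did not overlap and an official symbol (5 each way for the secondary ones). Added to these were the genes of the sorting gates, and of each other list the 4 members with the smallest p and, where a list checked for another cell type, its most abundant members. The comparisons, the test, the lists, the naming rule and all but 5 of the alternatives were chosen before the data were examined. The alternatives were quantile normalization, median centring, filters at the array median and at the 75th percentile, a pseudocount of 16, the mean of all probe sets, the most variable probe set, eBayes with trend and robust settings, array weights, fits of only the arrays compared, the replicate number as a block, and leaving out each array in turn. The 5 added later were the natural log scale, leaving out PL replicate 2 and EB replicate 1 together, the difference between the 3' and 5' ACTB probe sets as a covariate, a filter above the Bacillus controls, and the block with the EB numbers crossed. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.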

Results

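The 14 arrays fell into 6 groups of sorted CD34+CD38-CD90+ cells: FL (n = 3), FL-OP9 after 2 weeks (n = 3), FL-OP9 after 5 weeks (n = 2), EB-OP9 after 2 weeks (n = 2), EB (n = 2) and PL (n = 2). Between 64.2% and 73.6% of probe sets per array lay above the 95th percentile of that array's own Bacillus controls, with the lowest share in PL replicate 2. That percentile was 6.30 in PL replicate 2 and 5.09 to 5.72 in the other arrays, so the low share came in part from a higher cutoff. Correlations between arrays of a group ran from 0.898, in PL, to 0.989. The control probe sets for the ends of transcripts differed between groups. The log2 difference between the 3' and 5' probe sets of ACTB was 0.77 ± 0.02 (SD, n = 2) in EB against 2.08 ± 0.36 (n = 3) in FL and 2.03 ± 1.02 (n = 2) in PL. For STAT1 it was -1.20 ± 0.59 (n = 2) in EB, with group means from 0.86 to 1.77 elsewhere. For GAPDH the difference between the 3' and the middle probe set was 1.60 in PL replicate 2 and at most 0.35 in the other arrays, while that between the 3' and the 5' probe set was 0.321 in PL replicate 2 and 0.325 in FL replicate 3. All sizes below are log2 differences of the deposited values. The natural-log reading, which applies if the table was exponentiated with base e, is given for the leading genes.

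**Figure D1:**
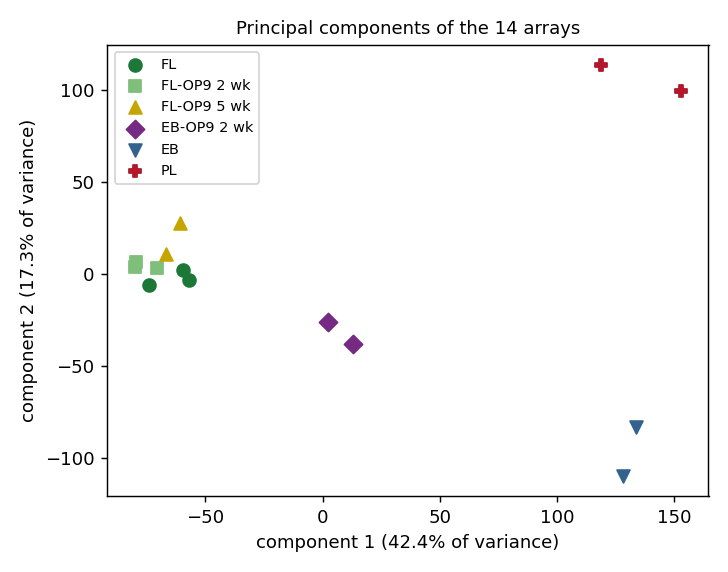
Principal components 1 (42.4% of variance) and 2 (17.3%) of the log2 values of all genes in the 14 arrays. Points are arrays coloured by group, and FL and FL-OP9 arrays lay together with EB, PL and EB-OP9 arrays apart from them.

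CD34, a surface marker common to both gates, was transcribed at a log2 level of 15.94 ± 0.46 (SD, n = 3) in FL, 16.51 ± 0.17 (n = 3) in FL-OP9 at 2 weeks, 15.88 ± 0.13 (n = 2) in EB-OP9 and 15.11 ± 0.78 (n = 2) in EB, but 11.27 ± 0.54 (n = 2) in PL. PTPRC, which encodes CD45, was 8.95 ± 2.88 in EB and 14.38 ± 1.24 in PL. THY1, which encodes CD90, was 12.68 ± 1.55 in EB and 12.39 ± 1.32 in PL against 9.47 ± 0.27 in FL.

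**Figure D2:**
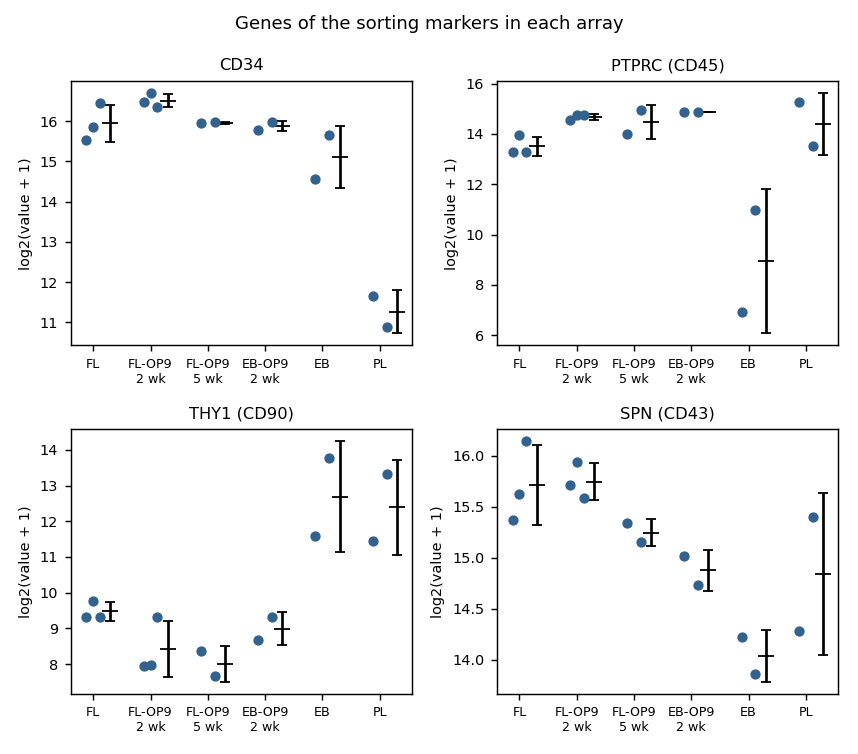
Log2 level (value + 1) of the gate genes CD34, PTPRC (CD45), THY1 (CD90) and SPN (CD43) in each array. Points are arrays, bars mean ± SD per group (n = 2 or 3); CD34 was 11.27 in PL and 15.11 to 16.51 in the other groups.

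The first comparison asked how EB-derived cells differ from FL-derived cells after the same 2 weeks on stroma and the same sort. In EB-OP9 cells (n = 2) the lists of megakaryocyte and interferon-response genes lay higher than in FL-OP9 cells (n = 3), with 11 of 17 and 12 of 25 genes past the test, and the list of stem cell regulators lay lower, with 10 of 34. With an estimated correlation only the megakaryocyte call held, and the adjusted p was 0.463 for the interferon and 0.139 for the stem cell list. HBE1, the embryonic epsilon globin, was higher by 9.99 ± 0.87 (SE, natural-log reading 6.95), and HOXB8 by at least 5.46. PKIB, an inhibitor of protein kinase A, was higher by 8.18 ± 0.73 and KYNU, an enzyme of tryptophan breakdown, by 9.04 ± 1.52. AGR2, a protein disulfide isomerase, and CA2, an erythroid carbonic anhydrase, were higher by at least 9.45 and 7.59. PROM1, which encodes the progenitor marker CD133, fell by 8.0 ± 0.72 (natural-log reading -5.55). MEG3, an imprinted noncoding RNA, fell by 9.75 ± 0.77, and the BMP antagonist CHRDL1 differed by at least -10.03. MLLT3 and MSI2, which maintain human stem cells, fell by 2.73 ± 0.39 and 2.18 ± 0.36. RAG1 and RAG2, the V(D)J recombinase of lymphoid precursors, fell by 3.14 ± 0.44 and 4.52 ± 0.51, and the cytokine receptor FLT3 fell by 3.43 ± 0.56. The T and NK cell gene CD2 went the other way, at 5.25 ± 0.36. The erythroid genes RHAG and HEMGN moved apart, RHAG higher by 5.56 ± 0.68 while HEMGN fell by 5.28 ± 0.63. The differences of the gate genes CD34 (-0.64 ± 0.38), PTPRC (0.20 ± 0.90), THY1 (0.57 ± 0.69) and SPN (-0.87 ± 0.36) did not pass the test.

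In this comparison 11 of 17 megakaryocyte genes rose (14 adjusted over the list alone, list median 3.06, or 2.99 with dim genes at their bound, camera adjusted p 2.29e-15, or p = 0.00575 with an estimated correlation), among them THBS1 (thrombospondin, 5.71 ± 0.43), SELP (P-selectin, 5.67 ± 0.60) and GP1BA (the platelet receptor for von Willebrand factor, 3.44 ± 0.34). Interferon-response genes rose in 12 of 25 cases (16 higher and 1 lower adjusted over the list alone, median 1.93, adjusted p 2.73e-11, but p = 0.463 with an estimated correlation), with IFI6 at 5.74 ± 0.49, IFI27 at 5.37 ± 0.65, HERC5 at 3.35 ± 0.35 and IFIT1 at 2.79 ± 0.36. MHC class II genes lay lower (1 of 11 fell, 1 adjusted over the list alone, median -2.22, adjusted p 0.00765, but p = 0.616 with an estimated correlation). So did MHC class I and antigen presentation genes (2 of 12 fell, 2 adjusted over the list alone, median -0.55, adjusted p 0.00765, but p = 0.59 with an estimated correlation). Of 34 regulators of haematopoietic stem cells (HSC) 10 fell and 1 rose (13 and 2 adjusted over the list alone, median -0.86, adjusted p 1.55e-07, but p = 0.139 with an estimated correlation). Lymphoid genes fell in 7 and rose in 1 of 26 cases (8 and 2 adjusted over the list alone, median -0.40, adjusted p 0.00765, but p = 0.136 with an estimated correlation). Of 5 globin genes 1 rose (1 adjusted over the list alone, median 1.49, adjusted p 0.00787, but p = 0.465 with an estimated correlation). Glycolysis and hypoxia genes were lower (2 of 22 fell, 9 adjusted over the list alone, median -1.20, adjusted p 2.85e-07, but p = 0.465 with an estimated correlation). Monocyte and macrophage genes were higher (5 of 23 rose, 11 adjusted over the list alone, median 2.60, or 2.28 with dim genes at their bound, adjusted p 2.3e-06, but p = 0.5 with an estimated correlation). Stromal genes rose in 4 and fell in 1 of 22 cases (6 and 1 adjusted over the list alone, median 0.99, or 0.64 with dim genes at their bound, adjusted p 0.0201, but p = 0.616 with an estimated correlation), a call lost without EB-OP9 replicate 2, where the median was 0.66. The HOXB cluster, with 3 genes higher and 1 lower of 10 (4 and 1 adjusted over the list alone, median 0.66, or 0.46 with dim genes at their bound), did not pass as a list (adjusted p 0.0652), although HOXB9 rose by 4.05 ± 0.52.

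By limma 1149 genes differed, 503 higher and 646 lower in EB-OP9, and the values of the groups did not overlap in any of them (45.1% of all genes did not overlap, against 20% by chance). The count was 528 and 541 without FL-OP9 2-week replicates 1 and 2, 684 and 332 without EB-OP9 replicates 1 and 2, 1985 without either PL array, which takes the PL spread out of the model, 3588 with array weights and 2184 with only the 5 arrays compared. The monocyte list median was 1.45 without EB-OP9 replicate 1 and 1.37 with the ACTB covariate, the glycolysis list median was -0.64 without EB-OP9 replicate 2, and fry called neither list, while the lymphoid list median was -0.81 and -0.07 without FL-OP9 2-week replicates 1 and 3.

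**Figure D3:**
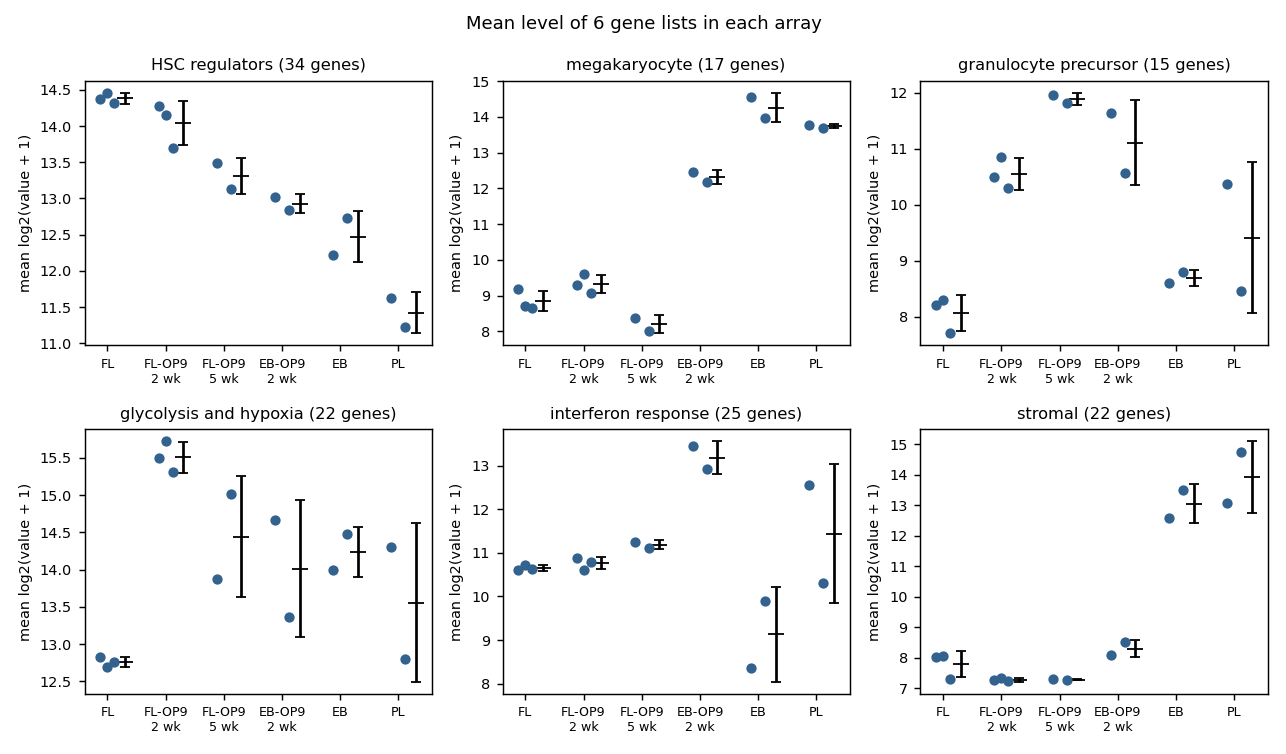
Mean log2 level (value + 1) over the genes of 6 lists in each array, with points for arrays and bars for mean ± SD per group (n = 2 or 3). Megakaryocyte genes averaged 12.31 in EB-OP9 and 9.32 in FL-OP9 at 2 weeks, and glycolysis and hypoxia genes 15.51 in FL-OP9 at 2 weeks and 12.76 in FL.

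The second comparison asked what 2 weeks on stroma changed in FL cells (n = 3 against 3). The lists of glycolysis and hypoxia and of granulocyte precursor genes lay higher, with 9 of 22 and 5 of 15 genes past the test, while 1 of 34 stem cell regulators passed. Both list calls were lost with an estimated correlation (adjusted p = 0.0508 each). BNIP3, a mitophagy receptor induced by hypoxia, rose by 5.67 ± 0.58 (SE, natural-log reading 3.93), the glucose transporter SLC2A3 by 5.07 ± 0.67, the aldolase ALDOC by 4.61 ± 0.59 and phosphoglycerate mutase PGAM1 by 2.20 ± 0.28. The granule proteins MPO and CTSG rose by 5.31 ± 0.65 and 4.65 ± 0.50, the defensin DEFA4 by 5.86 ± 0.70 and MS4A3, a marker of granulocyte and monocyte precursors, by 7.12 ± 0.89. JCHAIN, which links immunoglobulin subunits, and RAG2 were higher by at least 6.41 and 6.20, and the beta-adrenergic receptor ADRB1 by at least 5.17. The protease LGMN rose by 5.70 ± 0.63, HBD (delta globin) by 4.93 ± 0.53, the interferon-induced IFITM1 by 3.83 ± 0.31 and the serine synthesis enzyme PSAT1 by 4.39 ± 0.53. AASS, an enzyme of lysine breakdown, fell by 3.77 ± 0.32, and BEX5 and PPP1R9A differed by at least -4.41 and -3.10. TEK, the angiopoietin receptor of stem and endothelial cells, differed by at least -4.78, but did not pass with the mean of all probe sets (-2.88). None of the 5 gate genes passed under either adjustment (median 0.03, adjusted p 0.842), with CD34 at 0.57 ± 0.34, PTPRC at 1.17 ± 0.80 and THY1 at -1.06 ± 0.62.

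In FL-OP9 at 2 weeks 9 of 22 glycolysis and hypoxia genes rose (20 adjusted over the list alone, median 2.31, camera adjusted p 3.07e-31, or p = 0.0508 with an estimated correlation). Of 15 granulocyte precursor genes 5 rose (9 adjusted over the list alone, median 2.02, or 1.84 with dim genes at their bound, adjusted p 1.6e-11, or p = 0.0508 with an estimated correlation). Lymphoid genes rose in 2 of 26 cases (3 higher and 1 lower adjusted over the list alone, median 0.49, adjusted p 2.34e-05, or p = 0.0252 with an estimated correlation). Cholesterol synthesis genes rose in 1 of 17 cases (4 adjusted over the list alone, median 0.42, adjusted p 2.34e-05, or p = 0.0508 with an estimated correlation). Immediate early genes, which answer growth and stress signals within minutes, fell in 1 of 19 cases (10 adjusted over the list alone, median -1.34, adjusted p 1.54e-09, but p = 0.272 with an estimated correlation). Of 34 HSC regulators 1 fell (1 adjusted over the list alone, median -0.14, adjusted p 0.243), and of 25 interferon-response genes 1 rose (1 adjusted over the list alone, median -0.03, mean and test higher, adjusted p 0.461). No cell cycle gene of 30 passed alone, by limma over all genes or adjusted over the list alone, while the list lay higher (median 0.45, adjusted p 4.07e-05, but p = 0.531 with an estimated correlation), a call lost without FL-OP9 2-week replicate 3, where the median was 0.17. It was 0.90 without FL-OP9 2-week replicate 1, and that of the cholesterol list was 0.245 without FL-OP9 2-week replicate 3.

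By limma 147 genes changed in FL cells, 93 higher and 54 lower, and in none of them did the values of the groups overlap (24.7% of all genes did not overlap, against 10% by chance). The count was 66, 60 and 68 without FL replicates 1, 2 and 3, 75, 32 and 80 without FL-OP9 2-week replicates 1, 2 and 3, 448 without either PL array, 2225 with array weights and 662 with only the 6 arrays compared. The share of higher genes was 63.3% as deposited and 74.6% after median centring, the granulocyte list median was 3.74 after the filter at the 75th percentile, and fry did not call the immediate early and cell cycle lists.

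The third comparison asked what longer culture changed in FL cells, 5 weeks (n = 2) against 2 weeks (n = 3). PKIB rose by 5.85 ± 0.73 (SE, natural-log reading 4.06, adjusted p 0.0469 in limma) and GP1BA, the platelet receptor, fell by 2.84 ± 0.34 (natural-log reading -1.97, adjusted p 0.0469). The lists of stem cell and megakaryocyte genes lay lower at 5 weeks, and those of granulocyte, monocyte and cell cycle genes lay higher. The last 3 calls were lost with an estimated correlation (adjusted p = 0.102, 0.312 and 0.312). The HSC regulators had a median of -0.58 (0 of 34 fell, 1 adjusted over the list alone, camera adjusted p 9.66e-11, or p = 0.048 with an estimated correlation). The megakaryocyte list had a median of -0.65 (1 of 17 fell, 6 adjusted over the list alone, adjusted p 9.4e-08, or p = 0.048 with an estimated correlation). The HOXB cluster had a median of -0.60 (0 of 10 fell, 4 adjusted over the list alone, adjusted p 4.63e-05, or p = 0.0607 with an estimated correlation). Granulocyte precursor genes had a median of 1.48 (0 of 15 rose, 2 adjusted over the list alone, adjusted p 2.68e-08, but p = 0.102 with an estimated correlation). Monocyte and macrophage genes had one of 1.27 (0 of 23 rose, 6 adjusted over the list alone, adjusted p 2.78e-08, but p = 0.312 with an estimated correlation). Cell cycle genes had a median of 0.62 (0 of 30 rose under either adjustment, adjusted p 2.88e-09, but p = 0.312 with an estimated correlation). Glycolysis and hypoxia genes, higher at 2 weeks than in FL, had a median of -0.78 (0 of 22 fell under either adjustment, adjusted p 1.67e-08, but p = 0.312 with an estimated correlation), which was -1.59 without FL-OP9 5-week replicate 2, and -0.41 and not called without replicate 1. Lymphoid genes had a median of 0.28 (0 of 26 rose, 3 adjusted over the list alone, adjusted p 0.00158, or p = 0.048 with an estimated correlation), which was 0.11 and not called without FL-OP9 5-week replicate 2. The changes of CD34 (-0.56 ± 0.38) and THY1 (-0.41 ± 0.69) did not pass.

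With limma these 2 genes were all that passed between 2 and 5 weeks (1087 had an unadjusted p under 0.05), and both separated the groups (31.7% of all genes did, against 20% by chance). Changes of 3 log2 units were found for 80% of simulated genes in this comparison, where 122 simulated genes passed. With only 2 passing, the real data needed a smaller unadjusted p, so the 80% overstates what could be found here. No gene passed without any one FL, FL-OP9 2-week or EB-OP9 array (0 each), with quantile normalization, with a pseudocount of 16, with only the 5 arrays compared or with the replicate block. In contrast, 25 and 1 passed without FL-OP9 5-week replicates 1 and 2, 16 without either EB array, 43 without either PL array, 4 with the mean of probe sets and 851 with array weights. The HSC regulator median was -0.94 without FL-OP9 5-week replicate 1, the cell cycle median 0.35 and 0.97 without FL-OP9 2-week replicates 1 and 3, the megakaryocyte median -1.34 and the HOXB median -1.26 after the filter at the 75th percentile, and of the 8 lists given fry called only the megakaryocyte and lymphoid ones.

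The fourth comparison asked how EB cells (n = 2) differ from PL cells (n = 2) of the same CD43 gate. The lists of hepatocyte, endothelial and stem cell genes and of the HOXB cluster lay higher in EB, and those of macrophage, trophoblast and antigen presentation genes lay higher in PL. All 7 of these list calls were lost with an estimated correlation (adjusted p from 0.0592 to 0.401). The secreted liver and yolk sac proteins AFP and TTR were higher in EB by 9.62 ± 0.52 (SE, natural-log reading 6.68) and 9.40 ± 0.52, and fibrinogen FGB by 7.50 ± 0.55. LIN28A, an RNA-binding protein of embryonic stem cells, was higher by at least 9.73, and HAND1, a transcription factor of early mesoderm, by 7.05 ± 0.63. The vascular genes TIE1 and CDH5 were higher by 3.57 ± 0.37 and 4.46 ± 0.56, and HEY2, a Notch target of arteries, by 4.50 ± 0.56. The blood transcription factors GFI1 and GFI1B were higher by 5.54 ± 0.45 and 2.91 ± 0.39, HOXB4 by 3.92 ± 0.32 and HOXB9 by 5.86 ± 0.57. The macrophage scavenger receptor CD163 fell by 10.08 ± 0.91 (natural-log reading -6.99), the complement receptor VSIG4 fell by 7.84 ± 0.62 and CD14 fell by 7.82 ± 0.74. The chorionic gonadotropin subunit CGA differed by at least -10.22 and placental lactogen CSH1 by at least -6.51, and PAGE4 fell by 9.08 ± 0.68. TAP1 and PSMB9, which prepare peptides for MHC class I, fell by 4.54 ± 0.47 and 6.35 ± 0.74. CD34 was higher by 3.84 ± 0.42, and PTPRC fell by 5.43 ± 0.98 (-3.40 without EB replicate 1).

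In EB against PL 11 of 18 hepatocyte genes rose and 1 fell (11 and 1 adjusted over the list alone, median 5.65, camera adjusted p 1.09e-09, but p = 0.0794 with an estimated correlation). Of 22 endothelial genes 14 rose (15 adjusted over the list alone, median 2.61, adjusted p 5.09e-08, but p = 0.186 with an estimated correlation). Of 10 HOXB genes 6 rose (6 adjusted over the list alone, median 2.61, adjusted p 1.28e-05, but p = 0.0592 with an estimated correlation). Of 34 HSC regulators 13 rose and 3 fell (15 and 4 adjusted over the list alone, median 1.07, adjusted p 8.35e-05, but p = 0.242 with an estimated correlation). Cell cycle genes rose in 6 of 30 cases (8 adjusted over the list alone, median 0.87, adjusted p 5.95e-05, but p = 0.49 with an estimated correlation). Monocyte and macrophage genes fell in 14 and rose in 1 of 23 cases (16 and 1 adjusted over the list alone, median -4.51, adjusted p 5.51e-08, but p = 0.401 with an estimated correlation). The gene that rose was CYBB, at 1.91, but another of its probe sets was called lower, at -5.13. Trophoblast genes fell in 13 and rose in 3 of 22 cases (15 and 5 adjusted over the list alone, median -3.18, adjusted p 8.63e-07, but p = 0.0592 with an estimated correlation). MHC class I and antigen presentation genes fell in 8 of 12 (8 adjusted over the list alone, median -2.65, adjusted p 1.28e-05, but p = 0.401 with an estimated correlation). Of 18 Notch pathway genes 4 rose and 2 fell (5 and 4 adjusted over the list alone, median -0.11, mean 0.30 and test higher, adjusted p 0.646). Of 14 mast cell, basophil and eosinophil genes 1 rose and 3 fell (2 and 3 adjusted over the list alone, median -1.20, adjusted p 0.226).

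By limma 3724 genes differed between EB and PL, 1934 higher and 1790 lower in EB, and 3722 of them separated the groups (48.2% of all genes did, against 33.33% by chance). The count was 500 with array weights, 2347 with the ACTB covariate and 0 with only these 4 arrays, so all calls rest on the spread shared with other groups. The ACTB difference was 0.763 and 0.786 in the EB arrays, against 1.31 and 2.76 in the PL arrays. The slope of the covariate thus came almost wholly from groups other than EB, and it cannot decide on the EB signal. The MHC class I median was -1.25 without PL replicate 1, the endothelial median 4.06 without PL replicate 2 and EB replicate 1 together, the trophoblast median between -4.80 and -6.40 with the filters and the most variable probe set, and fry did not call the cell cycle list.

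The fifth comparison asked what 2 weeks on stroma changed in EB cells (n = 2 against 2), with the change of gate from CD43 to CD45 between them. The lists of hepatocyte, stromal, endothelial and megakaryocyte genes lay lower, with 11 of 18, 18 of 22, 14 of 22 and 8 of 17 genes past the test. Those of interferon-response, MHC class II, granulocyte and lymphoid genes lay higher, with 20 of 25, 4 of 11, 8 of 15 and 8 of 26. With an estimated correlation the interferon, MHC class II and granulocyte calls were lost (adjusted p = 0.118, 0.319 and 0.164). AFP fell by 9.93 ± 0.52 (SE, natural-log reading -6.89), the apolipoprotein APOA2 fell by 10.05 ± 1.02 and LIN28A fell by 9.63 ± 0.53. TTR differed by at least -10.12, and the matrix proteins LUM and POSTN by at least -7.47 and -7.53. Fibronectin FN1 fell by 7.19 ± 0.72, and RAMP2, a subunit of the adrenomedullin receptor, fell by 8.82 ± 0.62. The endothelial cadherin CDH5 fell by 4.30 ± 0.56, the Notch receptor NOTCH3 fell by 5.31 ± 0.54, and SOX7 and SOX17, which act in the endothelium that yields blood cells, differed by at least -5.40 and -3.56. The embryonic zeta globin HBZ fell by 8.22 ± 1.26 and the platelet tubulin TUBB1 fell by 3.34 ± 0.65. MPO and CTSG rose by 6.98 ± 0.80 (natural-log reading 4.84) and 7.22 ± 0.61. The myeloid nuclear protein MNDA, the chemokine receptor CCR2 and the pre-B cell receptor chain IGLL1 were higher by at least 8.31, 7.21 and 5.58. The interferon-induced genes IFI44, OAS1, SAMD9L and IFIT1 rose by 7.41 ± 1.09, 5.18 ± 0.61, 4.29 ± 0.31 and 4.06 ± 0.39. BCL11A, a repressor of fetal globin that also acts in stem and lymphoid cells, rose by 4.03 ± 0.49, and HLA-DRB1 by 5.87 ± 1.00. The adhesion molecules SELPLG and ITGA4 rose by 3.77 ± 0.40 and 2.69 ± 0.37. PTPRC, part of the second gate, rose by 5.92 ± 0.98, and by 3.89 without EB replicate 1.

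Among EB-OP9 cells 11 of 18 hepatocyte genes fell (13 adjusted over the list alone, median -6.05, or -5.39 with dim genes at their bound, camera adjusted p 6.4e-17, or p = 0.0369 with an estimated correlation), 18 of 22 stromal genes (19, median -5.19, or -4.61 at the bound, 7.73e-21, or p = 0.0398), 14 of 22 endothelial genes (19, median -3.01, 1.87e-15, or 0.0398) and 8 of 17 megakaryocyte genes (11, median -1.78, 2.04e-08, or 0.0369), with the values in the same order. Lymphoid genes rose in 8 of 26 cases (10 adjusted over the list alone, median 1.40, or 0.97 with dim genes at their bound, adjusted p 0.00137, or p = 0.0398 with an estimated correlation). Interferon-response genes rose in 20 of 25 (20 higher and 1 lower adjusted over the list alone, median 4.08, adjusted p 6.5e-15, but p = 0.118 with an estimated correlation). MHC class II genes rose in 4 of 11 (7 adjusted over the list alone, median 5.51, or 5.11 with dim genes at their bound, adjusted p 0.00019, but p = 0.319 with an estimated correlation). After this rise the list median in EB-OP9 was still below FL-OP9 at 2 weeks, at -2.22, and below fresh FL, at -1.71. Granulocyte precursor genes rose in 8 and fell in 1 of 15 cases (10 and 1 adjusted over the list alone, median 2.48, adjusted p 0.000216, but p = 0.164 with an estimated correlation). Erythroid genes fell in 5 of 17 cases (6 adjusted over the list alone, median -2.47, adjusted p 2.66e-05, but p = 0.171 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 17 (4 adjusted over the list alone, median -0.31, adjusted p 0.00246, but p = 0.118 with an estimated correlation). Of 34 HSC regulators 5 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.13, adjusted p 0.945). Of 22 glycolysis and hypoxia genes 1 fell (0 adjusted over the list alone, median -0.02, adjusted p 0.376), and no heat shock and chaperone gene of 14 passed under either adjustment (median 0.27 and mean 0.06, test lower, adjusted p 0.978).

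By limma 2696 genes differed between EB-OP9 and EB cells, 1552 higher and 1144 lower in EB-OP9, all with separate group values (56.8% of all genes were separate, against 33.33% by chance). The stromal list averaged 13.06 in EB, 13.92 in PL and 7.80 in FL. An effect of culture cannot be told apart from the change of gate, which may have let through different cells. The count was 1088 and 1241 without EB-OP9 replicates 1 and 2, 4339 without either PL array and 728 with only these 4 arrays, and the share of higher genes was 57.6% as deposited and 47.5% after quantile normalization. The endothelial median was -4.64 without EB replicate 1, the stromal median -3.23 with the mean of all probe sets, the cholesterol median -0.47 without EB replicate 2, and the lymphoid median 2.65 after the filter at the 75th percentile.

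The sixth comparison set PL cells (n = 2) against FL cells (n = 3), the in vivo sources, whose gates differed in CD43 and CD45. The lists of stromal, trophoblast, macrophage and megakaryocyte genes lay higher in PL, and that of stem cell regulators lay lower. Of these calls that of the macrophage list was lost with an estimated correlation (adjusted p = 0.182). CGA and LUM were higher by at least 10.22 and 9.23, FN1 by 11.58 ± 0.66 (SE, natural-log reading 8.04) and the collagen COL3A1 by 11.33 ± 0.88. The macrophage genes CD163, LYVE1, VSIG4 and CD14 rose by 10.65 ± 0.83, 11.20 ± 0.79, 8.86 ± 0.57 and 8.82 ± 0.68, and F13A1, coagulation factor XIII of macrophages and platelets, by 11.56 ± 0.81. THBS1 and the platelet integrin ITGB3 were higher by 9.74 ± 0.43 and 8.04 ± 0.68. The embryonic globins HBE1 and HBZ were higher by 12.32 ± 0.87 and 9.68 ± 1.15. The chemokine CCL2 was higher by 9.59 ± 1.38, and ALDH1A2 and RDH10, which make retinoic acid, by 5.36 ± 0.48 and 5.00 ± 0.43. PROM1 fell by 10.15 ± 0.72 (natural-log reading -7.07), the transcription factors GFI1, HLF and MLLT3 fell by 7.84 ± 0.41, 6.31 ± 0.89 and 5.56 ± 0.39, and the receptors FLT3 and KIT fell by 6.66 ± 0.56 and 5.35 ± 0.45. SPINK2, a protease inhibitor of primitive blood cells, fell by 6.66 ± 0.85, and HMGA2, a chromatin protein of fetal stem cells, fell by 3.50 ± 0.36. HOXB4 fell by 3.52 ± 0.29. CD34 fell by 4.68 ± 0.38 (adjusted p 9.2e-06 in limma).

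In PL against FL 18 of 22 stromal genes rose (20 adjusted over the list alone, median 6.08, or 5.75 with dim genes at their bound, camera adjusted p 2.08e-18, or p = 0.0486 with an estimated correlation). Of 17 megakaryocyte genes 15 rose (15 adjusted over the list alone, median 4.33, adjusted p 6.28e-16, or p = 0.00448 with an estimated correlation). Trophoblast genes rose in 16 and fell in 1 of 22 cases (18 and 1 adjusted over the list alone, median 4.70, or 3.93 with dim genes at their bound, adjusted p 6.28e-16, or p = 0.00448 with an estimated correlation). Of 34 HSC regulators 24 fell (27 adjusted over the list alone, median -2.54, adjusted p 7.79e-12, or p = 0.0434 with an estimated correlation). Genes of the retinoic acid pathway rose in 8 and fell in 2 of 19 cases (8 and 2 adjusted over the list alone, median 0.85, adjusted p 0.000204, or p = 0.0461 with an estimated correlation). Monocyte and macrophage genes rose in 16 of 23 (18 adjusted over the list alone, median 6.31, or 6.15 with dim genes at their bound, adjusted p 7.55e-13, but p = 0.182 with an estimated correlation). Globin genes rose in 4 of 5 (4 adjusted over the list alone, median 6.76, adjusted p 4.14e-05, but p = 0.182 with an estimated correlation). Genes of NF-kB and inflammation rose in 11 of 18 (11 adjusted over the list alone, median 4.72, adjusted p 4.93e-07, but p = 0.29 with an estimated correlation). All 22 stromal genes, 21 of 22 trophoblast genes and 22 of 23 monocyte and macrophage genes lay above the control level in both PL arrays, against 16, 13 and 17 in all FL arrays. The pluripotency list (2 of 14 fell, 2 adjusted over the list alone, median 0.11, mean -0.31, test higher, adjusted p 0.943), the fetal stage list (2 rose and 5 fell of 12, the same adjusted over the list alone, median -0.45, adjusted p 0.312) and the adhesion and niche receptor list (2 rose and 4 fell of 18, 3 and 4 adjusted over the list alone, median 0.12, adjusted p 0.943) did not pass.

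By limma 5195 genes differed between PL and FL, 1932 higher and 3263 lower in PL, and 5173 of them separated the groups (45.0% of all genes did, against 20% by chance). The count was 1855 with array weights and 2486 with only these 5 arrays. The stromal and trophoblast medians were 3.39 and 2.68 with the mean of all probe sets, the retinoic acid median 2.64 after the filter at the 75th percentile, and the NF-kB median 2.56 without PL replicate 1.

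Against fresh FL, FL-OP9 cells at 5 weeks (n = 2 against 3) had more of CD1C and CD1E, genes of lipid antigen presentation, by at least 9.91 and 8.37. JCHAIN was higher by at least 7.66, while EPPK1, a cytoskeletal linker, fell by 6.68 ± 0.67 (SE) and PRTG differed by at least -5.62. Granulocyte precursor genes rose in 9 of 15 cases (11 adjusted over the list alone, median 3.60, or 3.15 with dim genes at their bound, camera adjusted p 1.16e-14, or p = 0.0489 with an estimated correlation). Lymphoid genes rose in 7 of 26 (7 adjusted over the list alone, median 0.92, adjusted p 3.29e-07, or p = 0.00903 with an estimated correlation). HSC regulators fell in 6 of 34 (11 adjusted over the list alone, median -0.67, adjusted p 2.79e-07, but p = 0.0979 with an estimated correlation). By limma 576 genes changed, 327 higher and 249 lower. The count was 314, 276 and 316 without FL replicates 1, 2 and 3, 301 and 66 without FL-OP9 5-week replicates 1 and 2, 1256 without either PL array, 2753 with array weights, 1218 with only these 5 arrays and 349 with the replicate block. After median centring 68.6% in place of 56.8% were higher, the median over all genes was 0.06 in place of -0.08, and the lymphoid list median was 2.12 after the filter at the 75th percentile.

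EB-OP9 cells (n = 2) against fresh FL (n = 3) had more of the platelet chemokine PPBP, by 10.47 ± 1.19 (SE), PKIB, by 9.54 ± 0.73, and HBE1, by 9.45 ± 0.87, while MEG3 fell by 10.54 ± 0.77 and CHRDL1 differed by at least -9.09. Megakaryocyte genes rose in 11 of 17 cases (14 adjusted over the list alone, median 2.19, camera adjusted p 9.2e-15, or p = 0.0066 with an estimated correlation). HSC regulators fell in 15 of 34 (17 adjusted over the list alone, median -1.11, adjusted p 2.11e-09, but p = 0.117 with an estimated correlation). Interferon-response genes rose in 14 of 25 (15 higher and 2 lower adjusted over the list alone, median 2.36, adjusted p 6.18e-11, but p = 0.333 with an estimated correlation). Amino acid response genes, which answer a lack of amino acids, rose in 5 of 21 (5 adjusted over the list alone, median 0.60, adjusted p 0.00115, but p = 0.315 with an estimated correlation). By limma 1662 genes differed, 781 higher and 881 lower, and after median centring the median over all genes was 0.10 in place of -0.03. The count was 1033 and 1082 without FL replicates 2 and 3, 867 and 614 without EB-OP9 replicates 1 and 2, 2664 without either PL array and 3259 with array weights, and the megakaryocyte median was 3.43 after the filter at the 75th percentile.

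The culture effects in FL and EB cells share no arrays and were compared across genes, which are not independent replicates. Over 19726 genes Pearson's r of the log2 differences was 0.25 and Spearman's rho 0.24. Both effects were called for 62 genes, 24 higher in both against 7.32 for independent lists, 26 lower in both against 3.13, and 12 in opposite directions against 9.64. The 62 became 23, 28 and 28 without FL replicates 1, 2 and 3, 31, 18 and 34 without FL-OP9 2-week replicates 1, 2 and 3, 35 and 34 without EB-OP9 replicates 1 and 2, 200 without either PL array, 395 with array weights, 95 with only the groups compared and 35 with the replicate block. The opposite pairs were 31 against 46.61 without either PL array, so their small excess did not hold. MPO, CTSG and MS4A3 rose in both. The origin effects, EB-OP9 against FL-OP9 and EB against PL, correlated at 0.14 by both measures. Of 472 genes called in both, 139 were higher in both against 49.32 for independent lists, 180 were lower in both against 58.62, and 153 went opposite ways against 108.98. The 472 became 236 and 231 without FL-OP9 2-week replicates 1 and 2, 300 and 164 without EB-OP9 replicates 1 and 2, 844 and 794 without PL replicates 1 and 2, 188 with array weights and 0 with only the groups compared. The excess of opposite pairs was gone without PL replicate 1 (247 against 272.6) and with array weights (45 against 45.64).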

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

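The tests of monocytes or macrophages among EB-OP9 cells, of fewer CD34-positive cells, of EB cells already high before culture, of the ACTB covariate and of other splits of the arrays were chosen after the results were seen, and the other tests before. The results of the next 2 paragraphs were picked out because the effect of culture differed between EB and FL cells in a test of that difference. The gate changed from CD43 to CD45 between EB and EB-OP9 but not between FL and FL-OP9. A different response to culture therefore cannot be told apart from the change of gate.

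In limma's test 898 genes differed in their culture effect between EB cells (EB-OP9 minus EB, n = 2 against 2) and FL cells (FL-OP9 at 2 weeks minus FL, n = 3 against 3). Of these 441 changed upward and 457 downward in EB relative to FL. The count was 531, 486 and 581 without FL replicates 1, 2 and 3, 433 and 431 without FL-OP9 2-week replicates 1 and 2, 365 and 381 without EB-OP9 replicates 1 and 2, and 2099 without either PL array. The largest differences upward were IFI44 at 8.15 (7.41 ± 1.09 (SE) in EB, -0.74 ± 0.89 in FL), MX2 at 7.53, CIITA at 7.50, LILRA2 at 6.91 and STEAP4 at 6.84. The largest downward were COLEC12 at -10.16, APOA2 at -10.08 (-10.05 ± 1.02 in EB, 0.04 ± 0.83 in FL), TTR at -9.90, LIN28A at -9.79 and P4HA2 at -9.70. For CIITA, LILRA2, STEAP4, COLEC12, TTR, LIN28A and P4HA2 at least 1 of the 4 groups lay below the control level. Their sizes and ranks are those of the model and rest in part on values below that level. COLEC12 lay above it only in EB (12.17) and STEAP4 only in EB-OP9 (10.15). MX2 and STEAP4 did not pass without EB-OP9 replicate 1 (7.18 and 6.32). LILRA2 did not pass without FL replicate 1 or 2, FL-OP9 2-week replicate 1, either EB-OP9 array or EB replicate 2, and CIITA without any 1 of the 12 arrays other than PL.

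List medians of this difference that camera called follow with the genes past the test over all genes, then over the list alone. They were 4.11 for interferon response (16 higher and 1 lower of 25, then 18 and 1), 5.01 for MHC class II (3 higher of 11, then 5) and 1.49 for MHC class I and antigen presentation genes (4 higher of 12, then 4). Lower were hepatocyte genes at -5.47, or -5.17 with dim genes at their bound (11 of 18, then 11 with 1 higher), stromal at -3.56 (10 of 22, then 18), globin at -3.17 (2 of 5, then 3) and glycolysis and hypoxia at -2.12 (6 of 22, then 10). Endothelial genes were at -1.76 (4 lower of 22, then 13), megakaryocyte at -1.47 (4 of 17, then 7), erythroid at -1.39 (4 of 17, then 5) and cholesterol synthesis at -0.99 (5 of 17, then 7). Notch pathway genes were at -0.98 (2 lower of 18, then 6 with 2 higher), fetal stage at -0.64 (0 of 12, then 2), amino acid response at -0.15 (2 of 21, then 5) and pluripotency at -0.09 (1 of 14, then 1). Trophoblast genes were at 0.04 (3 lower of 22, then 3), where the mean was -0.65 and the test lower. With an estimated correlation the hepatocyte, megakaryocyte and cholesterol lists passed (adjusted p 0.0237 each), and the others had an adjusted p from 0.0518 (stromal) to 0.386 (MHC class I and II). The pluripotency and trophoblast calls ended without EB replicate 1, where the medians were 0.130 and 0.175. Without EB replicate 1 the medians were also -2.76 for endothelial, -0.60 for erythroid, -0.95 for megakaryocyte, 0.90 for MHC class I, -1.63 for Notch and -0.54 for amino acid response genes. Without EB replicate 2 they were -2.20 for erythroid, -0.29 for Notch and -0.55 for pluripotency genes. That of fetal stage genes was -0.43 without FL-OP9 2-week replicate 1, and that of amino acid response genes -0.01 without EB-OP9 replicate 2.

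The list of interferon-response genes lay higher in EB-OP9 than in FL-OP9 cells at 2 weeks (12 of 25 rose, 16 higher and 1 lower adjusted over the list alone, median 1.93), a call lost with an estimated correlation (adjusted p 0.463). The list median was at least 1.94 under quantile normalization and median centring. Array medians already averaged 7.55 in EB-OP9 and 7.59 in FL-OP9 at 2 weeks. Rescaling this already normalized table could therefore hardly move the list median, and scaling between arrays is left undecided. A single EB-OP9 array as the whole cause is argued against by a list median of at least 1.80 without either array. Monocytes or macrophages among the sorted EB-OP9 cells, which the CD34+ gate would remove, cannot be told apart from a response of the sorted cells. Their 3 most abundant genes had a median difference of 1.67 and did not pass: LYZ was 17.77 against 16.11 (1.67 ± 1.26), AIF1 17.93 against 17.79 (0.15 ± 0.45) and FCER1G 15.43 against 13.72 (1.71 ± 0.64), and FL cells express all 3. The whole monocyte and macrophage list had a median of 2.60, with 5 of 23 genes called higher (11 adjusted over the list alone). Its camera call was lost with an estimated correlation (adjusted p 0.5). A difference of EB from FL origin stays open and untested.

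The lists of stromal, trophoblast and macrophage genes lay higher in PL than in FL cells, with 18 of 22, 16 of 22 and 16 of 23 genes called higher (20, 18 and 18 adjusted over the list alone) and 1 trophoblast gene called lower, and the macrophage call was lost with an estimated correlation (adjusted p 0.182). RNA quality of PL replicate 2 as the whole cause is argued against by list medians of at least 4.20 without that array. Cells of other types among the sorted PL cells, which the CD34+CD43+CD90+ gate would remove, cannot be told apart from expression by the sorted cells, since either would put the genes above the control level: 97.0% of the 67 list members (65) lay above the control level in both PL arrays, 46 in all FL arrays, with FN1 at 18.27, CGA at 15.59 and COL3A1 at 17.43 in PL, while AIF1, abundant in FL as well, was 17.42 against 18.11. Fewer CD34-positive cells as the whole reason for the lower HSC regulators stay open: 3 of these genes fell beyond CD34 by over 2 SE, but they are the top of the list, and other cells that carry CD34 would have the same effect. The difference of gate and tissue stays open as well.

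The culture effect on the list of glycolysis and hypoxia genes was lower in EB than in FL cells (6 of 22 genes lower in this difference, 10 adjusted over the list alone, median -2.12). The camera call was lost with an estimated correlation (adjusted p 0.121). Under quantile normalization and median centring the median came no nearer to 0 than -2.13. Array medians of these groups already averaged from 7.55 in EB-OP9 to 7.67 in FL, so rescaling could hardly move it and scaling is left undecided. With the ACTB covariate the median was -1.94. The ACTB difference was 0.763 and 0.786 in the EB arrays, so the slope of the covariate came almost wholly from other groups. It cannot decide on the 3' to 5' signal of the EB arrays. Before culture the list median was 1.17 higher in EB than in FL. That value is itself a term of the difference of culture effects, so it restates the pattern and is no separate test of a cause. The list's median levels were 13.09 in FL, 15.96 in FL-OP9 at 2 weeks, 14.28 in EB and 14.31 in EB-OP9. The oxygen conditions of sources and cultures, and the change of gate between EB and EB-OP9, stay open and untested here.

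For FL-OP9 at 2 weeks against FL, 1 of the 10 splits of the 6 arrays, the real one, gave as many as its 147 genes, and the highest other gave 1. These 10 splits are too few for a share under 0.05.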

How the results depend on the processing

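The natural log scale, leaving out PL replicate 2 and EB replicate 1 together, the ACTB covariate, the filter above the Bacillus controls and the block with EB numbers crossed were tests chosen after the data were seen. Directions of the named genes held in nearly all settings, but for many of them this could hardly be otherwise. The largest rises and falls between 2 groups were chosen for values that do not overlap. Leaving out or reweighting arrays cannot turn their sign, so it is no test of these directions. Counts moved with the estimate of the spread. Signal over background is a limit of the arrays beside their number: 64.2% to 73.6% of probe sets lay above the control level, and differences among dim genes are bounds. Where leaving out an array left 1 in a group, that group was assumed to vary like the others. Array weights, fits of only the arrays compared and the leaving out of a PL array change which arrays set the spread. For all other moves the cause was not tested.

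EB-OP9 against FL-OP9 at 2 weeks gave 1149 genes, from 332 to 1985 without single arrays, 3588 with array weights, 2184 with only the groups compared and 2716 without PL replicate 2 and EB replicate 1 together. FL-OP9 at 2 weeks against FL gave 147, from 32 to 448 without single arrays, and 2225, 662 and 811 in those settings, 83 with the replicate block, 75 with EB numbers crossed and 235 with the ACTB covariate. FL-OP9 at 5 against 2 weeks gave 2, from 0 to 43 without single arrays, 851 with array weights, 86 without the 2 arrays together, 4 with the mean of probe sets and 4 with the ACTB covariate. It gave 0 with quantile normalization, 0 with a pseudocount of 16, 0 with only the groups compared, 0 with the replicate block and 0 with EB numbers crossed. EB against PL gave 3724, from 2585 to 5432 without single arrays, 500 with array weights, 0 with only the groups compared and 2347 with the ACTB covariate. EB-OP9 against EB gave 2696, from 1088 to 4339 without single arrays, 728 with only the groups compared and 4243 without the 2 arrays together.

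PL against FL gave 5195, from 4083 to 6102 without single arrays, 1855 with array weights and 2486 with only the groups compared. FL-OP9 at 5 weeks against FL gave 576, from 66 to 1256 without single arrays, 2753 with array weights, 1218 with only the groups compared, 349 with the block, 379 with EB numbers crossed and 1936 without the 2 arrays together. EB-OP9 against FL gave 1662, from 614 to 2664 without single arrays, 3259 with array weights and 3586 without the 2 arrays together. The difference of culture effects gave 898, from 365 to 2099 without single arrays, 1784 with only the groups compared, 580 with the block and 2653 without the 2 arrays together.

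Same-numbered deviations of FL and FL-OP9 2-week arrays correlated at 0.085, 0.094 and -0.022, within the range of -0.168 to 0.122 over all pairs. The highest value, 0.122, was that of FL and FL-OP9 5-week arrays. FL-OP9 arrays at 2 and 5 weeks gave 0.098, and FL-OP9 5-week and EB arrays 0.1. The replicate numbers were not taken as pairs, but these values do not exclude pairing. With the replicate block the counts of the 9 comparisons were 900, 83, 0, 3087, 2153, 4280, 349, 1243 and 580, in the order above.

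With an estimated correlation camera kept 21 of its 131 list calls. In all 91 lists were called by fry, which lost 53 of the 131 and gained 13 others, and between 119 and 138 by camera without single arrays. Many medians, above all of lists that did not pass, moved by over 1.5 times or changed sign without single arrays. Called lists turned sign in some settings as well, among them the next 3. The interferon list in PL against FL had a median of -0.012 without PL replicate 1 (lowest -0.012 and highest 1.575 over single arrays), and the MHC class II list 0.273 without PL replicate 2, alone or with EB replicate 1 (lowest -6.956, highest 0.273). The list median, NF-kB and inflammation, EB-OP9 vs EB, was 1.228 with the ACTB covariate. STRA6 in EB against PL was -1.129 with the mean of probe sets and -2.901 with the most variable one, HOXB7 in EB-OP9 against EB 0.544 with the most variable, and CYP19A1 there 0.04 and 0.619. The correlation of culture effects was 0.21 with quantile normalization and 0.2108 without the 2 arrays together, and from 0.2021 to 0.279 without single arrays. That of origin effects was 0.1644 with the filter at the 75th percentile, 0.0912 without the 2 arrays, 0.2311 with the ACTB covariate and 0.1535 above the Bacillus controls, and from 0.0998 to 0.1492 without single arrays.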

Other observations

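Of the tests in this part only the ACTB covariate was chosen after the result was seen. Several gene groups that the comparisons above left out also differed between sources or between EB-OP9 and EB (PL n = 2, FL n = 3, EB n = 2, EB-OP9 n = 2). Genes of the heat shock response rose in PL against FL in 4 of 14 cases (4 adjusted over the list alone, median 0.62, camera adjusted p 0.000347, but p = 0.29 with an estimated correlation), with the co-chaperone BAG3 at 5.50 ± 0.64 (SE) and HSPH1 at 2.53 ± 0.38. Notch pathway genes rose in 4 and fell in 1 of 18 cases (the same adjusted over the list alone, median 0.71, adjusted p 0.00318, but p = 0.182 with an estimated correlation), with the ligand JAG1 at 5.30 ± 0.57 and the target HEY1 at 7.57 ± 1.11. Without PL replicate 1 the calls of the heat shock and Notch lists ended, at medians of 0.44 and 0.63.

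Fetal stage genes rose in 6 of 12 cases in EB against PL (7 adjusted over the list alone, median 1.498, adjusted p 0.000635, but p = 0.0592 with an estimated correlation), with the RNA-binding proteins IGF2BP1 at 1.71 ± 0.30 and IGF2BP2 at 1.77 ± 0.32. That call ended without PL replicate 1, at a median of 0.91. Immediate early genes fell in 6 of 19 cases in EB-OP9 against EB (11 lower and 1 higher adjusted over the list alone, median -1.72, adjusted p 3.9e-08, but p = 0.164 with an estimated correlation), with the nuclear receptor NR4A1 at -5.87 ± 0.79 and the matrix protein CCN1 at -5.69 ± 0.63. The median of that list was -1.08 with the ACTB covariate.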
